A study of Danio rerio with 2 samples.

How the data were processed

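Single-cell RNA sequencing was done on wild-type zebrafish of the AB strain at 2 stages, 12 and 72 hours post fertilization (hpf). Per the labels' protocols, optic vesicles were dissected at 12 hpf and retinas at 72 hpf, the cells were passed through a strainer, and libraries were made with the 10x Genomics Chromium 3-prime chemistry, version v2. The tissue label of the 12-hpf sample reads retina, although the protocol names optic vesicles. There was 1 library per stage, so no difference between stages has a replicate check and no p-value was computed.

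The deposited tables hold whole-number counts of unique molecular identifiers (UMIs) per gene and cell. Their sums per cell differ between cells, and the values were used as raw counts. Cell Ranger, Seurat and the genome build Zv9 are named per the submitters' processing notes. Versions, mapping settings and the thresholds of the authors' filters are not given in the sources used here. The deposited 12-hpf table is named as one from which unwanted cells had been removed, and both full tables as filtered, so cell and gene filters preceded every value given here. In the 12-hpf table each gene had UMIs in at least 4 cells and in the 72-hpf table in at least 2 cells. A smaller deposited table for each stage holds 713 genes at 12 hpf and 263 genes at 72 hpf for the same cells, with values equal to those of the full table, and was not used further.

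The 12-hpf table holds 2270 cells, 13791 genes and 27263139 UMIs, with a median of 11349.5 UMIs per cell (range 6129 to 23841). The 72-hpf table holds 2586 cells, 14070 genes and 12656187 UMIs, with a median of 4081 UMIs per cell (range 2251 to 19071). The median depth at 12 hpf was thus 2.78 times that at 72 hpf. Median detected genes per cell were 2372.5 and 1313. Mitochondrial genes took 2.38% and 2.10% of UMIs, and ribosomal protein genes 36.8% and 30.1%. No further cells were removed for the main results.

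Stages were compared over the 11714 genes present in both tables. The 2077 genes listed only at 12 hpf held 0.268% of the UMIs of that library, and the 2356 genes listed only at 72 hpf held 2.46%. Because gene filters were applied to each table separately, absence from a table was not read as absence of expression. UMIs were summed over all cells and scaled by the library's total over the shared genes to CPM in its usual definition. Genes with under 3 UMIs in both libraries were to be left out, which removed no gene. A library at 0 would have been set to 3 counts. Over the total of each whole table, rather than of the shared genes, this corresponds to 0.110 CPM at 12 hpf and 0.237 CPM at 72 hpf. Fold changes carry exact conditional binomial 95% intervals and CPM values exact Poisson 95% intervals. Over the named genes these Poisson bounds lay within 6.24% of the value where it rested on 1000 or more UMIs and within 20.8% where it rested on at least 100 but under 1000. They were wider below that, and are printed there for most of the genes. All intervals cover counting error only.

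Before the data were examined, 20 process lists and 26 cell type marker lists were fixed, along with the rule for named genes. Of the 736 gene names in these lists, 568 matched by symbol or listed alias, 7 by letter case, 23 by a synonym in the RefSeq gene table of assembly GRCz12tu, and 138 had no match. Matching by case and synonym was added after the gene names of the tables, but not their values, had been seen. For each process list, the median log2 fold of 72 over 12 hpf was set beside the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list is called higher or lower where its median left the central 95% of the random medians. The median log2 fold of all shared genes was 0.24 under CPM scaling, so list medians are given relative to it. Named genes were the 3 measured members of each process list with the highest mean over the libraries, and the 8 genes with the largest fold in each direction among those in at least 10% of cells and at 100 CPM or more in the higher library. A gene that this rule names is not reported here. Genes outside this rule are said to be so where they are named.

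Each library was clustered by itself with scanpy 1.11.5 (anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, Python 3.11.15). Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering at resolution 1.0 were used with a fixed seed. No author annotation of cells was used. A marker counted for a cluster when it was in at least 25% of its cells and at least 2-fold above the other cells, and a cluster was called X-like when at least 3 markers of a list did so, no other class had as many, and its 10 leading genes by fold held no more markers of another class. The naming rule was changed several times after clusters had been seen: matches made by cell cycle genes alone were first excluded, ties between classes were then refused, and lists matched by cell cycle genes alone were then left out of the tie count. Clusters of the 12-hpf library changed with numerical precision until double precision was used, and stayed without a name in each version, so they are described by their leading genes only. Scrublet called 14 doublets at 12 hpf (0.617%) and 9 at 72 hpf (0.348%), which were kept in the main clustering.

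Regional lists were compared within the 12-hpf library by the mean Spearman correlation of gene pairs across cells, over genes with UMIs in at least 20 cells, beside 1000 random gene sets matched on detection. Shares of cells with cell cycle UMIs were taken after thinning each cell to 2000 UMIs, at which no cell was lost, and a cell counted with 2 or more UMIs over the list. Variable genes were counted as those with variance over mean above 1.5 at a mean of at least 0.05 UMIs, in 2270 cells per library thinned to 2000 UMIs. Matplotlib 3.10.9 drew the plots.

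The steps were tested on simulated data. In simulated stage counts over 11665 genes, 97% of the changed genes came out within 0.5 of their true log2 fold, and 7 of 100 lists of unchanged genes left the central range. Over 3000 simulated genes, 200 of 200 overdispersed genes and 0 Poisson genes passed the variability limit. The changed genes were drawn from well-counted genes and given large changes, and the overdispersed genes were those with the highest means. Neither result covers genes near the limits. Alternatives fixed beforehand covered library summary, gene filter, scaling, clustering resolution, components, depth, doublets, correlation type and thresholds. Comparing 12-hpf cells with 72-hpf progenitor and precursor clusters, and leaving out the rows mcm5 and hsp70l, were chosen after seeing the data. The progenitor and precursor clusters are the retinal progenitor-like and neurogenic precursor-like ones plus the unnamed cluster with the most pcna UMIs per cell, 509 cells in all, of which 199 are unnamed. Leaving the genes that selected these clusters out of the lists was also chosen after seeing the data. No coordinates are given, since the reference table at hand is of another assembly than the deposited values.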

Results

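Transcriptomes of single cells were compared between the zebrafish optic vesicle at 12 hpf, when it is an epithelial outgrowth of the forebrain, and the retina at 72 hpf, when its neurons are differentiating. The title of the series puts the question as the equipotency of cells in developing optic vesicles. The 12-hpf library held 2270 cells and 27263139 UMIs, and the 72-hpf library 2586 cells and 12656187 UMIs. There was 1 library per stage, no difference between stages has a replicate check, and all intervals are 95% intervals for counting error only.

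Genes of neuronal output and light detection were far higher in the 72-hpf library. All 11 compared synaptic vesicle genes and 16 of 17 compared phototransduction genes were higher at 72 hpf, with list medians 6.31 and 6.16 log2 units above the median of all genes. The SNARE gene snap25b was at 964 CPM at 72 hpf against 0.147 CPM (0.0401 to 0.377) at 12 hpf, and the calcium sensor syt1a at 242 against 0.441 CPM (0.228 to 0.771). Synaptophysin b, sypb, was at 182 against 0.368 CPM (0.176 to 0.676). Among phototransduction genes, the transducin gamma gene gngt2b reached 1666 CPM at 72 hpf against 0.699 CPM (0.421 to 1.09), the recoverin gene rcv1 593 against 0.147 CPM (0.0401 to 0.377), and pde6g 519 against 0.625 CPM (0.364 to 1.0). The level of pde6g does not come from photoreceptor-like cells alone. It was at 8976 CPM in a horizontal-like cluster of 37 cells at 72 hpf, against 1001 CPM in photoreceptor-like cells. The first value is of a single cluster with pde6g among its leading genes. The second is pooled over all 5 photoreceptor-like clusters, which include dividing cells. A further 25 phototransduction genes and 14 synaptic genes were listed only in the 72-hpf table, while 2 (pde6b and guca1e) and 1 (cplx4c) were listed only in the 12-hpf table. The medians of both lists lay above all 10000 matched random lists. The makeup of the 72-hpf library enters these values. Against the 509 cells of its progenitor, precursor and dividing unnamed clusters, a choice made after seeing the data, the synaptic median was 3.79 and the phototransduction median 2.26. Both were still above the random range. In those cells gngt2b was at 134 CPM and rcv1 at 38.2 CPM, near their 136 and 37.3 CPM of all genes in ganglion-like cells. For pde6g the levels were 121 and 60.7 CPM. Free RNA was not subtracted, and whether it accounts for these 2 medians was not tested.

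The optic vesicle library carried far more transcript of genes for making ribosomes. All 26 compared genes of the nucleolus and ribosome biogenesis list were at least 2-fold higher at 12 hpf, and their summed level was 14427 CPM at 12 hpf against 1598 CPM at 72 hpf. Nucleophosmin, npm1a, was at 2950 against 152 CPM (19.4-fold, 18.5 to 20.3), nucleolin, ncl, at 2068 against 351 CPM (5.88-fold, 5.71 to 6.07), and nop10, a component of the H/ACA small nucleolar particles, at 1193 against 181 CPM (6.60-fold, 6.32 to 6.89). The list median lay 3.31 log2 units below that of all genes, written -3.31, and below all random lists. Among 9 compared early embryonic and stem cell genes, 7 were higher at 12 hpf (median -2.45, percentile 0.01). These included the SoxB1 gene sox3 (4.65-fold, 4.33 to 5.01), the DNA methyltransferase gene dnmt3b (8.33-fold, 7.08 to 9.87) and the chromatin protein gene hmga1a (1.73-fold). The direction of hmga1a turned against the 72-hpf progenitor, precursor and dividing unnamed clusters alone (log2 0.0582). The pluripotency factors pou5f3 and nanog, and klf4b, ved and vox, were listed only in the 12-hpf table.

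Energy metabolism genes went the other way. Of 20 compared glycolysis genes, 16 were at least 2-fold higher at 72 hpf, and the list median lay 3.20 log2 units above that of all genes (percentile 100). The glyceraldehyde-3-phosphate dehydrogenase gene gapdhs was at 2070 CPM at 72 hpf against 53.2 CPM (38.9-fold, 36.9 to 41.0) and the enolase gene eno1a at 606 against 2.5 CPM (242-fold, 191 to 312). The aldolase gene aldoaa was 1.41-fold higher at 12 hpf. Of 40 nuclear genes of oxidative phosphorylation, 39 were higher at 72 hpf by CPM and 36 relative to the median of all genes, with a list median of 0.74 (percentile 100). Its most abundant members differed little: atp5g3b was 1.42-fold higher at 72 hpf, and cox7c (1.1-fold) and cox6b2 (1.01-fold) turned to the 12-hpf side with median-ratio scaling. Against the same 509 cells of the 72-hpf library the glycolysis median was 1.83 and the oxidative phosphorylation median 0.38. Both were still above the random range.

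Genes of Fgf, Wnt, Hedgehog and Notch signalling were mostly higher at 12 hpf. Of 13 compared Fgf genes 12 were higher there (median -2.15, percentile 0), among them the receptor fgfr2 at 88.3 against 1.78 CPM (1.12 to 2.70), the target etv5b (6.18-fold, 5.11 to 7.54) and the feedback inhibitor spry2 (2.08-fold). Of 9 Hedgehog genes 8 were higher (median -3.31, percentile 0), among them the co-receptors cdon (6.70-fold, 5.86 to 7.69) and boc (8.43-fold, 7.09 to 10.1) and the transducer smo (5.21-fold). Of 17 Wnt genes 12 were higher by CPM and 13 relative to all genes (median -1.16, percentile 0.415). Within that list the secreted frizzled-related gene sfrp5 was at 189 against 0.405 CPM (0.132 to 0.945), the receptor fzd8a was 5.58-fold and the transcription factor tcf7l2 3.69-fold higher at 12 hpf. Of 25 Notch genes 19 were higher at 12 hpf (median -0.95, percentile 0.41), including the hairy-related repressors her15.2 (2.0-fold), her15.1 (1.51-fold) and her12 (2.85-fold, 2.78 to 2.92). The makeup of the 72-hpf library enters these values: against its progenitor and precursor clusters and the unnamed dividing cluster of 199 cells, 509 cells in all and a choice made after seeing the data, the Notch median was 0.40 and lay above the random range (percentile 99.3), opposite to the main call, and her15.2 (log2 0.53) and her15.1 (0.91) turned. These clusters were named in part by 6 members of the Notch list (dla, dlb, dld, her6, her9 and hes6), and without them the median was 0.33, inside the random range (percentile 96.1). The Wnt median was then -0.32, inside the random range.

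Genes of the eye field did not move as a group. Of 19 compared eye field and progenitor transcription factors 8 were higher at 12 hpf and 11 at 72 hpf, and the list median of 0.29 lay inside the random range (percentile 93.7). The eye field gene six3b was 1.58-fold higher at 12 hpf (1.53 to 1.65). At 72 hpf pax6a was 7.93-fold higher (7.48 to 8.41) and vsx1, which marks bipolar cells in the mature retina, 46.0-fold higher (40.7 to 52.1). Chosen after their values were seen, the retinal homeobox genes rx3, at 215 against 26.4 CPM, rx1, at 159 against 56.3 CPM, and rx2, at 115 against 30.7 CPM over all genes of each table, were all higher at 12 hpf. Against the same 509 cells alone the list median was -0.37, inside the random range.

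**Figure D1:**
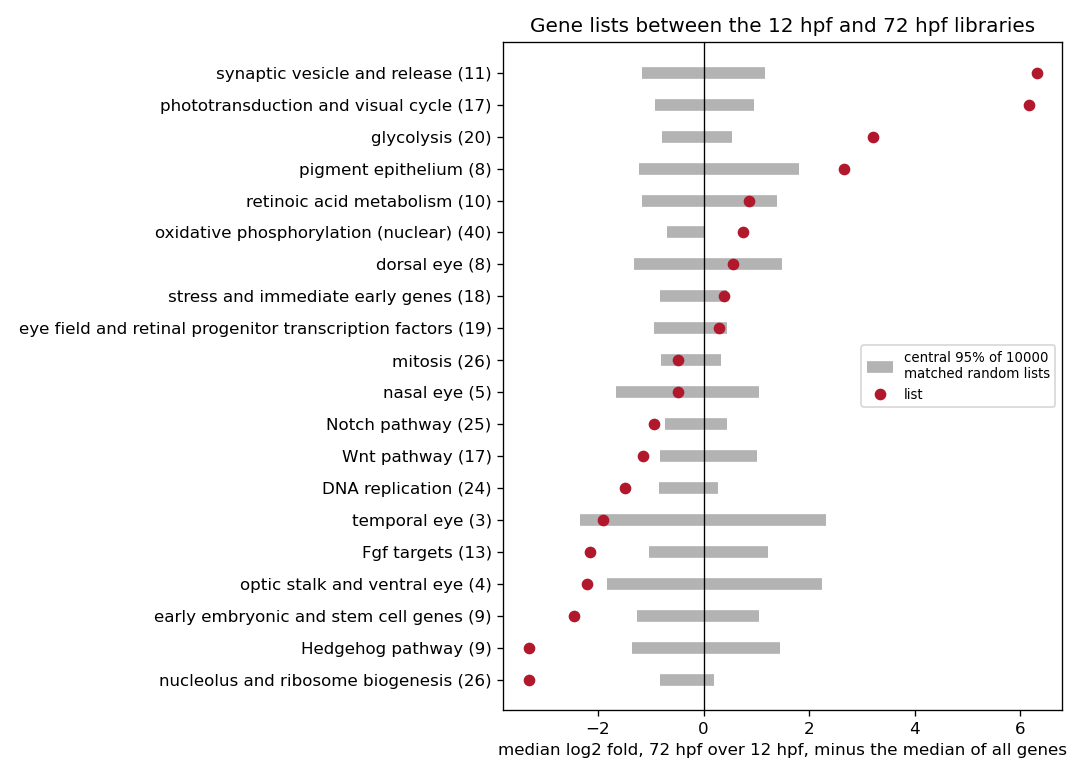
Median log2 fold of 72 hpf over 12 hpf of each gene list, minus the median of all 11714 shared genes (points, with the number of compared genes in brackets), beside the central 95% of 10000 random lists matched on expression (grey bars). Synaptic (6.31) and phototransduction (6.16) genes lie farthest to the 72-hpf side, and nucleolar and Hedgehog genes (both -3.31) farthest to the 12-hpf side.

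Regional genes of the eye differed between stages in both directions. Pigment epithelium genes were higher at 72 hpf in 6 of 8 compared (median 2.66, percentile 99.6), with the premelanosome gene pmela at 44.7 against 1.62 CPM (1.18 to 2.17), bhlhe40 10.3-fold (8.70 to 12.2) and otx2 5.35-fold (4.66 to 6.15) higher. A cluster of 53 cells held 87.3% of the 72-hpf UMIs of pmela, but 7.17% of those of bhlhe40 and 1.54% of those of otx2. Most UMIs of bhlhe40 and otx2 thus lay outside the cluster with most melanin UMIs. The melanin genes dct, tyrp1b, slc45a2 and slc24a5 and the visual cycle gene rpe65a were listed only at 72 hpf. Optic stalk and ventral genes were higher at 12 hpf in 3 of 4 (median -2.21, percentile 1.01): pax2a was at 32.6 against 0.891 CPM (0.445 to 1.59), the retinaldehyde dehydrogenase gene aldh1a3 8.57-fold (7.05 to 10.5) and vax1 1.81-fold (1.56 to 2.12) higher. The medians of the dorsal (0.55, 8 genes), nasal (-0.49, 5 genes) and temporal (-1.90, 3 genes) lists stayed inside the random range. Members of these lists differed all the same: the forkhead gene foxg1b was 17.0-fold higher at 72 hpf (15.7 to 18.4), while efna5a, an ephrin of the nasal retina, was 20.9-fold (16.1 to 27.7), foxd1 3.17-fold (2.84 to 3.56) and the Eph receptor row epha3l 3.16-fold (2.70 to 3.74) higher at 12 hpf. The temporal gene epha4b was near 1.6 CPM in both libraries and its direction turned with the mean per cell. Dorsal bambia (2.69-fold) and tbx2a (2.02-fold) and nasal hmx4 (1.41-fold) were higher at 72 hpf, and efnb2a (1.16-fold, 85.1 against 73.2 CPM) turned with median-ratio scaling. Against the 509 cells of the progenitor, precursor and dividing unnamed clusters hmx4 turned to the 12-hpf side (log2 -0.97). Retinoic acid genes were higher at 72 hpf in 8 of 10, inside the random range (median 0.86, percentile 91.3), with rdh10a and raraa each 2.03-fold higher. Against those 509 cells raraa turned (log2 -0.74) and the list median of 1.01 left the random range.

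Stress and immediate early genes were higher at 72 hpf in 14 of 18 by CPM, inside the random range (median 0.38, percentile 96.4). The heat shock gene hsp70l was among the most abundant of all lists, at 4157 CPM at 12 hpf and 8706 CPM at 72 hpf. The chaperone hsp90aa1.2 was 1.28-fold and the co-chaperone dnajb1b 1.09-fold higher at 72 hpf, and dnajb1b turned with median-ratio scaling.

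Genes present in both tables were also ranked by fold, within the limits on share of cells and CPM given above. Genes listed at 1 stage only could not enter, such as opn1lw2, at 922 CPM, and arr3a, at 452 CPM, of the whole 72-hpf table. The ranked genes farthest to the 72-hpf side were snap25b (6555-fold, 2560 to 24064), the beta-synuclein gene sncb (4380-fold, 2125 to 10896), rcv1 (4030-fold, 1573 to 14793), the G protein gene gnb3a (2851-fold, 1113 to 10466), the calretinin gene calb2b (2414-fold, 1108 to 6579), gngt2b (2384-fold, 1527 to 3961), gng3 (2079-fold, 1095 to 4549) and the neurogranin gene nrgna (1451-fold, 666 to 3957). Those far to the 12-hpf side included sfrp5 (467-fold, 200 to 1439), the laminin gene lamb1a.1 (193-fold, 93.5 to 480), a row named HSPA8 (1 of 2) (120-fold, 84.7 to 177), the collagen chaperone gene serpinh1b (111-fold, 96.9 to 128), the BMP receptor gene bmpr1ba (83.5-fold), stm (83.3-fold) and the small heat shock gene hspb1 (78.6-fold, 72.9 to 84.8). Levels below 1 CPM rest on few UMIs, which the wide intervals show, and free RNA in the suspension was not subtracted.

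Cells with mitosis transcripts made up a larger share of the optic vesicle library. At 2000 UMIs per cell, 60.9% of 12-hpf cells (58.8 to 62.9, exact Clopper-Pearson, 1382 of 2270) had 2 or more mitosis UMIs against 19.4% of 72-hpf cells (17.9 to 21.0, 501 of 2586). Without thinning the shares were 94.1% and 27.1%. Among 72-hpf ganglion-like cells, which should not divide, the share was 2.25% (1.03 to 4.23) at a median of 3750 UMIs before thinning, against library medians of 11349.5 and 4081. The share with DNA replication UMIs was 99.96% at 12 hpf and 99.5% at 72 hpf, which was set by the row mcm5. Without that row, a choice made after seeing the data, it was 95.8% (94.9 to 96.6) at 12 hpf and 24.2% (22.6 to 25.9) at 72 hpf, and 9.50% in ganglion-like cells.

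Levels of replication genes followed the same direction and those of mitosis genes less so. Of 24 DNA replication genes 19 were higher at 12 hpf by CPM and 21 relative to all genes (median -1.49, percentile 0). The polymerase clamp pcna was at 842 against 491 CPM (1.71-fold, 1.67 to 1.76) and rpa3, of the single-strand binding complex, at 359 against 148 CPM (2.42-fold, 2.31 to 2.55). The row mcm5 went the other way, 3503 against 9482 CPM, and correlated across cells with hsp70l (Spearman 0.66 and 0.73) while all its correlations with mcm2, mcm3, mcm4, mcm6 and mcm7 were below 0, so its name is doubtful here. The row mcm5.1 behaved like mcm5 (0.54 and 0.60 with hsp70l). The row mcm5.2 went with the other mcm genes (0.27 to 0.50 at 12 hpf and 0.44 to 0.63 at 72 hpf) and, like most of the list, was higher at 12 hpf, 141 against 40.8 CPM of each whole table. Of 26 mitosis genes 16 were higher at 12 hpf by CPM and 19 relative to all genes, with a median of -0.48 inside the random range (percentile 20.4). With the mean of per-cell CPM the median was -0.87, below that range (percentile 1.8). The proliferation marker MKI67, at 285 against 153 CPM, was 1.86-fold and the ubiquitin-conjugating enzyme ube2c 1.38-fold higher at 12 hpf, and the spindle gene nusap1 1.3-fold higher at 72 hpf. Against the 509 cells of the progenitor, precursor and dividing unnamed clusters, whose selection used pcna and is thus partly circular, the replication median was -0.00600, inside the random range, and the mitosis median 0.85, above it. The directions of pcna (log2 0.69), MKI67 (0.31) and ube2c (0.74) turned in that comparison.

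The 72-hpf library split into 23 clusters, most of which carried markers of known retinal classes. Amacrine-like cells formed 25.2% of the library (23.5 to 26.9, 651 of 2586 cells), photoreceptor-like cells 18.8% (17.3 to 20.4), ganglion-like cells 15.5% (14.1 to 16.9), neurogenic precursor-like cells 9.94% (8.81 to 11.2), bipolar-like cells 8.39% (7.35 to 9.53), horizontal-like cells 5.26% (4.43 to 6.19), Müller glia-like cells 3.09% (2.46 to 3.84) and retinal progenitor-like cells 2.05% (1.54 to 2.67). The last share was 5.45% to 9.81% at resolution 2.0, with 10 or 40 components and in deeper cells. In cells at or above the median depth, horizontal-like cells were 2.09% and no cluster was named bipolar-like. The bipolar-like cluster had a median of 2539 UMIs and the larger horizontal-like one 2762. Both lie under that cut of 4081 UMIs, so most of their cells were left out. At the main settings the remaining 11.8% (10.6 to 13.1) in 3 clusters stayed unnamed. No cluster met the rule for lens, blood, endothelium, epidermis, mesenchyme, neural crest or pigment epithelium at the main settings. The clusters were named by their markers, so the genes that follow identify them and are not findings. The 5 leading genes by fold held the GABA transporter gene slc6a1a and gad2 in 1 of 4 amacrine-like clusters, gbx2, meis2b and tfap2c in another, neurod2 and the glycine transporter gene slc6a9 in another, and kif26aa and ednrb1a in the smallest. Of 3 ganglion-like clusters, 1 had pou4f2 and pou4f1 among them, another eomesa and slc17a6b, and another kcnip3a and oaz2b, while pou4f1 and pou4f2 were among the raised markers of all 3. They held gnb3a, samsn1a and vsx1 in the bipolar-like cluster, and ompa and rprmb or hmx3 and onecutl in the horizontal-like ones. Among the photoreceptor-like clusters, 1 was led by cnga3b, pde6c, grk7a and gnb3b, and another by the ultraviolet opsin gene opn1sw1. The Müller glia-like cluster had ca14 and rhbg among its leading genes, and the retinal progenitor-like one fabp11a.1, col4a6 and rgrb. That last cluster of 53 cells also held most UMIs of melanin genes in the library, 87.3% of pmela, 88.1% of dct and 92.8% of tyrp1b, but 1.54% of otx2 and 7.17% of bhlhe40. UMIs of pmela were in 24.5% of its cells (median 7466 UMIs) against 1.93% of the other cells (median 4058 UMIs), so its name covers a mixed group. The largest unnamed cluster had 199 cells, was led by mybl2, e2f7 and cdc6, and carried neurogenic and progenitor markers in near equal number.

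Mitosis transcripts at 72 hpf were concentrated in some of these classes. Mitosis UMIs at 2000 UMIs per cell were found in 61.9% of neurogenic precursor-like cells (55.6 to 67.8), 41.5% of retinal progenitor-like cells (28.1 to 55.9) and 40.2% of unnamed cells, against 3.23% of amacrine-like, 2.76% of bipolar-like, 2.25% of ganglion-like and 1 of 80 Müller glia-like cells. The neurogenic precursor-like share was 100% in the clusters led by pif1 and parpbp, but 6.67% (2.72 to 13.3) in the one led by fkbp1ab. Among unnamed clusters the share was 61.8% in the one of 199 cells, and 0% in those of 67 and 40 cells. Photoreceptor-like cells stood at 26.7% (22.9 to 30.9) and horizontal-like cells at 22.1% (15.4 to 30.0). Within them the share was carried by single clusters. A photoreceptor-like cluster led by slc29a2, with the thyroid hormone receptor gene thrb among its 5 leading genes, had 80.2% and one with cdkn3 and cdc20 among them 100%, while the opn1sw1 cluster had 2.84%. Of the horizontal-like clusters, the one with hmx3 and onecutl had 75.7% and the one with ompa 2.02%. Cell cycle genes were not removed before clustering, and cells called as doublets were kept. Some clusters had genes of the mitosis list among their 10 leading genes. These were cenpe and tacc3 in the one led by parpbp, and cdc20 and kpna2 in the photoreceptor-like one with cdkn3. High mitosis shares of such single clusters are thus partly set by the clustering.

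**Figure D2:**
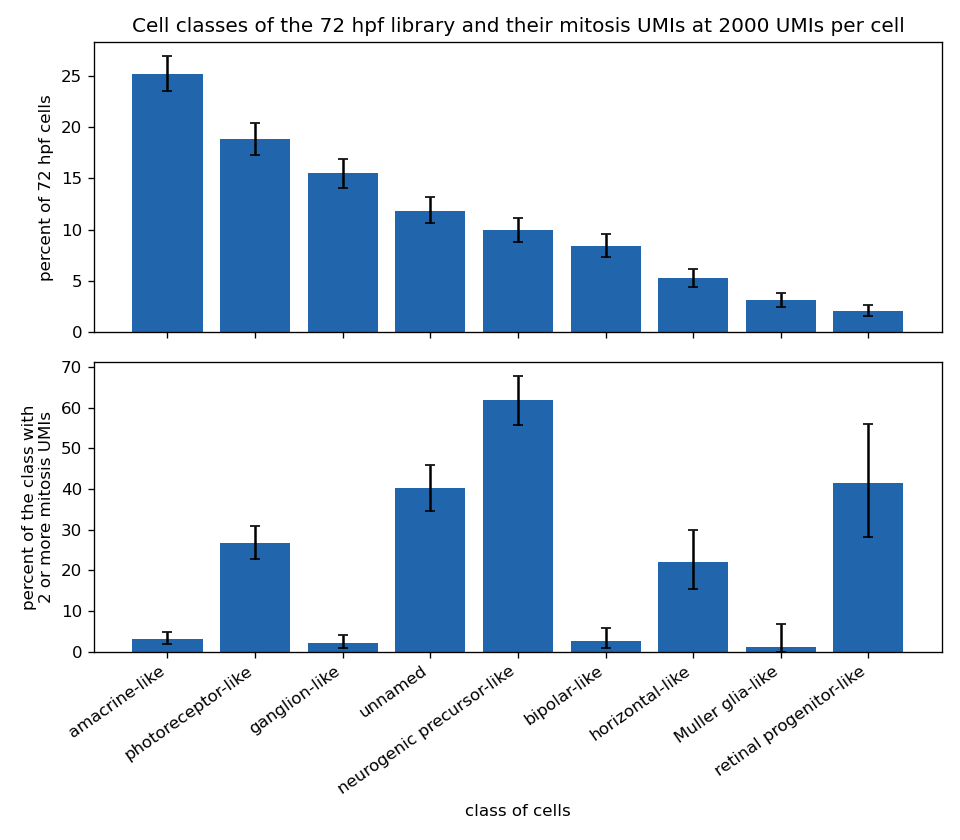
Upper bars give the percent of the 2586 cells of the 72-hpf library in each marker-named class, and lower bars the percent of each class with 2 or more mitosis UMIs at 2000 UMIs per cell. Error bars are exact 95% intervals for counting error. Amacrine-like cells are the largest class (25.2%), and neurogenic precursor-like cells have the highest mitosis share (61.9%).

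The deposited cells of the optic vesicle differed far less from one another than those of the later retina. At equal depth and cell number, 36 of 3168 genes (1.14%) had a variance over mean above 1.5 at 12 hpf, against 690 of 3624 (19.0%) at 72 hpf. Only the 12-hpf table is named as one from which unwanted cells had been removed, by criteria not given in the sources used here, and the effect of that removal on these counts was not measured. At 12 hpf the most variable were the heat shock gene hsp70l.1 (3.43), the Notch pathway repressor genes her15.2 (3.17), her12 (3.14) and her4.3 (3.10). At 72 hpf they were the blue cone opsin gene opn1sw2 (226), the rod opsin gene rho (178), the somatostatin gene sst3 (134) and gngt2b (111). The 13 clusters of the 12-hpf library reached 3 markers of no cell type list, optic vesicle included, at the main settings. A marker had to be 2-fold above the other cells of the same library. Markers shared by most cells, such as six3b in 97.6% and rx1 in 80.1%, can hardly meet that rule. The lack of names is thus no sign that these cells lack optic vesicle genes or are alike. Cell cycle genes led several of the 13 clusters, such as cks2, tacc3 and kpna2 in 336 cells and e2f8, cdc6 and rrm2.1 in 200 cells. Regional genes were among the leading genes of others: pax2a (2.66-fold above the other cells) and foxg1a in 182 cells, rbp1a (2.82-fold) and foxd1 (2.28-fold) in 152 cells, and mab21l2 (3.99-fold) in 111 cells. Cells with mitosis UMIs after thinning made up 76.9%, 86.8% and 80.2% of these clusters in turn, against 60.9% of the 12-hpf library. The cluster of 152 cells also had rrm2.1 among its leading genes. Regional genes and mitosis transcripts were thus not separated in these clusters. Boundaries between the 13 clusters depended on numerical precision.

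Nasal and temporal genes tended to be detected in different cells of the optic vesicle at 12 hpf. The mean Spearman correlation was 0.136 among nasal genes and 0.0994 among temporal genes, and -0.0937 between nasal and temporal genes, the last below all 1000 matched random gene sets. The forkhead genes foxg1a, nasal, and foxd1, temporal, had a correlation of -0.34, and 43 of 2270 cells had UMIs of both. Nasal hmx4 and hmx1 correlated at 0.38, foxd1 and the Eph receptor row epha3l at 0.30, and hmx4 with foxd1 at -0.32. UMIs of nasal efna5a were found in 61.8% and of hmx4 in 51.8% of cells, and of temporal foxd1 in 41.7% and epha3l in 28.3%. No cluster of this library was named, so background was read from cells with UMIs of the opposite gene. Of 946 cells with foxd1 UMIs 4.55% (3.31 to 6.07, median 11771 UMIs) had foxg1a UMIs, against 32.4% (29.9 to 35) of the 1324 cells without (median 11035 UMIs). For foxd1 the shares were 9.11% (6.67 to 12.1) of the 472 cells with foxg1a UMIs and 50.2% of the cells without. These groups were chosen after seeing the data, and such shares are upper limits of background for these genes only. After thinning to 2000 UMIs per cell, nasal with temporal genes still lay below the random range (-0.033) and temporal genes above it (0.043). The nasal list with itself (0.0146) did not leave that range. The temporal list then held 3 genes rather than 4.

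Optic stalk and dorsal genes were negatively correlated, outside the random range at full depth only. Their mean correlation was -0.0353 (percentile 0), against 0.0514 within optic stalk and ventral genes and 0.0553 within dorsal genes (both percentile 100). After thinning these were -0.00997, 0.0177 and 0.00478, all inside the random range. The stalk list then held 3 genes rather than 4, and the dorsal list 4 rather than 6. The ventral gene aldh1a3 went with nasal foxg1a (0.27), and the stalk list with the nasal list (0.0310, percentile 99.4), as did the dorsal list (0.0387, percentile 99.9), both inside the random range after thinning (0.0132 and 0.000803). Stalk genes were not alike in this: vax1 went against nasal hmx4 (-0.24) and hmx1 (-0.15). Stalk genes and temporal genes (-0.0169, percentile 0) and dorsal and temporal genes (-0.00953, percentile 0.2) lay below the random range, and after thinning the first was 0.00405, inside it. The stalk members split here too, with aldh1a3 against temporal foxd1 (-0.24) and epha3l (-0.16), and vax1 with foxd1 and foxd2 (both 0.18). In shares of cells, aldh1a3 was at 42.0% and pax2a at 22.6%, dorsal efnb2a at 51.2% and bambia at 21.3%, and the eye field genes six3b at 97.6% and rx1 at 80.1%. Pigment epithelium genes, of which otx1a was in 23.0% and otx1b in 10.6% of cells, correlated among themselves (0.0486, percentile 100), went against nasal (-0.0192) and stalk genes (-0.0130), both at percentile 0, and went with temporal genes (0.0154, percentile 98.0). After thinning the first 3 of these were 0.00415, -0.00786 and -0.00431, all inside the random range, while pigment with temporal genes stayed above it (0.0145). Eye field genes correlated at 0.0213 among themselves, 0.0225 with dorsal, 0.0277 with nasal genes, a list that shares hmx4, and -0.00613 with stalk genes. With dorsal (0.00335) and nasal genes (0.00424) they were inside the random range after thinning. They were inside the random range with pigment (0.00127) and temporal genes (0.00516), as were pigment with dorsal genes (0.00328). Of the 21 values, 12 entered the random range after thinning, where every list but the nasal one held fewer genes.

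**Figure D3:**
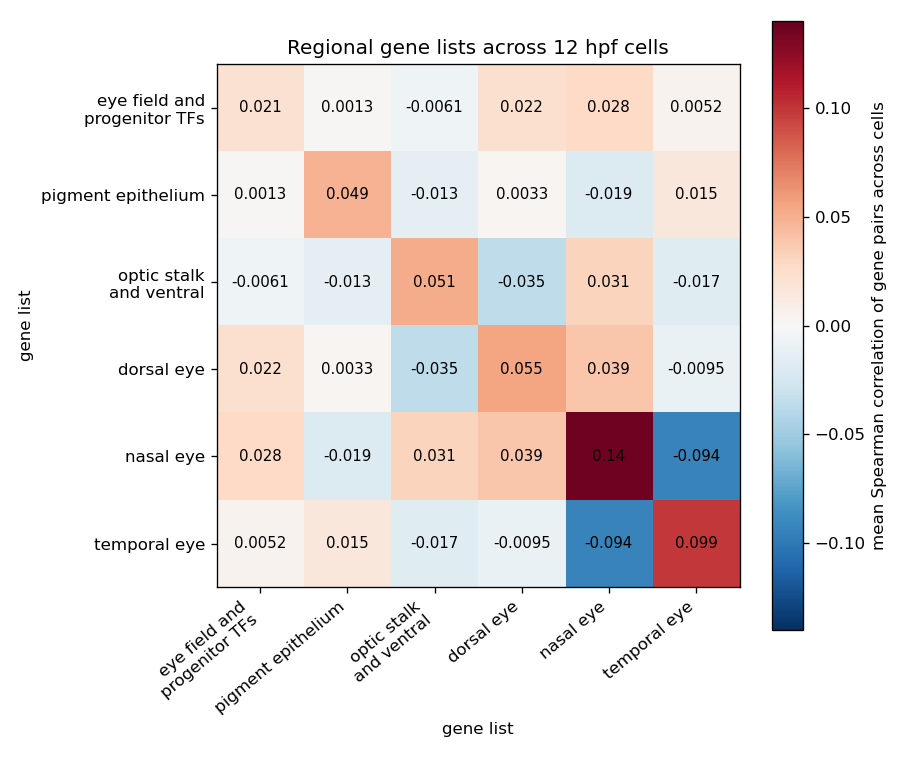
Mean Spearman correlation across the 2270 cells at 12 hpf of gene pairs within and between the regional lists, with red above and blue below 0. The nasal list with itself (0.136) is the highest value and nasal with temporal (-0.0937) the lowest.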

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

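Comparisons with the 72-hpf progenitor and precursor clusters (the retinal progenitor-like and neurogenic precursor-like clusters and the unnamed cluster of 199 cells led by mybl2), and those without the rows mcm5 and hsp70l, were chosen after seeing the data; the others were planned. No paired analysis was possible because there was 1 library per stage and no result comes from a test. For gene lists, 133 alternative values kept the direction and the side of the random range and 9 did not. All 20 lists did so without a gene filter, with at least 20 UMIs, with both other scalings and without the rows mcm5 and hsp70l. Many of the 133 values could not differ, so their number is no measure of stability. The values without a gene filter repeat the main ones, since that filter removed no gene. Both scalings by construction cannot move a list against the median of all genes. Leaving out the rows mcm5 and hsp70l changes only the DNA replication and stress lists. With the mean of per-cell CPM the mitosis median was -0.87 and left the random range. Against the progenitor and precursor clusters (509 cells, 19.7% of the 72-hpf cells) the eye field (-0.37), mitosis (0.85) and Notch (0.40) medians changed sign, with mitosis and Notch now above the random range, DNA replication (-0.00600) and Wnt (-0.32) entered the random range and retinoic acid (1.01) left it. Without the genes that selected these clusters, also chosen after seeing the data, the Notch median (0.33) still differed in sign but lay inside the random range, and DNA replication was at -0.0127. That choice drops the differentiated cells by construction. Otherwise the cause was not tested. The pseudocount alternative did not apply to counts, and leaving out clusters of other tissues changed nothing, since none was named.

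Named genes that changed direction are given as log2 of 72 over 12 hpf. With median-ratio scaling, which moves every gene by the same amount, efnb2a was at -0.0194, dnajb1b at -0.11, cox7c at -0.10 and cox6b2 at -0.22. With the mean per cell epha4b was at 0.31. Against the progenitor and precursor clusters pcna was at 0.69, MKI67 at 0.31, ube2c at 0.74, hmga1a at 0.0582, her15.2 at 0.53, her15.1 at 0.91, efnb2a at -0.0180, hmx4 at -0.97, raraa at -0.74, hsp90aa1.2 at -0.16, dnajb1b at -0.33, cox7c at -0.48 and cox6b2 at -0.23.

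Cell classes depended on the settings. Apart from the cut on depth, which drops cells, the cause was not tested. At resolution 0.5 amacrine-like cells were 29.1%, horizontal-like 8.24%, photoreceptor-like 15.7% and unnamed cells 7.19%. At resolution 2.0 Müller glia-like cells were 1.51%, neurogenic precursor-like 13.1%, photoreceptor-like 16.9%, retinal progenitor-like 5.45% and unnamed cells 9.82%. With 10 components horizontal-like cells were 3.98%, photoreceptor-like 15.7%, progenitor-like 6.65% and unnamed 9.44%. With 40 components amacrine-like cells were 20.5%, progenitor-like 8.47% and unnamed 9.20%. In cells at or above the median depth, Müller glia-like cells were 4.02%, amacrine-like 29.9%, ganglion-like 12.1%, horizontal-like 2.09% and progenitor-like 9.81%, no cluster was bipolar-like, and 97.0% of 12-hpf cells were unnamed, the rest optic vesicle-like. That cut left out most cells of the bipolar-like cluster (median 2539 UMIs) and of the horizontal-like cluster with ompa (median 2762 UMIs). Without called doublets amacrine-like cells were 27.8% and unnamed 9.27%. Microglia-like cells were named only at resolution 2.0 (0.619%), with 10 components (0.657%) and with 40 components (0.696%).

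All 21 regional values kept their side with Pearson correlation. After thinning, 12 entered the random range: eye field with dorsal (0.00335) and nasal (0.00424), pigment with itself (0.00415), stalk (-0.00431) and nasal (-0.00786), stalk with itself (0.0177), dorsal (-0.00997), nasal (0.0132) and temporal (0.00405), dorsal with itself (0.00478) and nasal (0.000803), and nasal with itself (0.0146). Thinning leaves fewer UMIs for every gene, and fewer genes then entered the comparison. The pigment list held 4 genes rather than 7 and the dorsal list 4 rather than 6. The stalk and temporal lists each held 3 rather than 4, and the eye field list 17 rather than 18. Only the nasal list kept its 5 genes. Most thinned values thus do not cover the same genes, and whether depth alone accounts for these changes was not tested.

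The share of cells with mitosis UMIs at 12 and 72 hpf was 79.1% and 35.7% from 1 UMI, 49.2% and 16.4% from 3 UMIs, 94.1% and 27.1% without thinning, and 43.6% and 15.4% at 1000 UMIs. For DNA replication it was 100% and 99.8% from 1 UMI, 100% and 99.9% without thinning, 98.7% and 98.4% at 1000 UMIs, 95.8% and 24.2% without mcm5, and without mcm5 or thinning 41.0% at 72 hpf. Variable genes numbered 85 and 1048 at the lower limit, 17 and 396 at the limit of 2, and 18 and 323 at 1000 UMIs, which follows from the construction of these settings.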

Other observations

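Tests of the row mcm5, the comparison of amacrine-like with ganglion-like cells and the range without gnb1a and gnb1b were chosen after the results were seen; the other tests below were set before theirs.

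Some further members of the lists are named here after their values were seen. Within the Notch list the delta gene dla was at 56.7 CPM at 72 hpf against 12.7 CPM at 12 hpf, and hes6 at 232 against 44.6 CPM, opposite to the her genes. Among early embryonic genes lin28a was at 19.0 CPM at 12 hpf and 0.553 CPM at 72 hpf. Pyruvate kinase, pkma, was at 5.87 against 207 CPM and lactate dehydrogenase, ldha, at 9.87 against 131 CPM. In the 12-hpf library mitosis UMIs were in 98.8% of the cluster led by cks2, tacc3 and kpna2, and in 20.6% of the cluster led by casp8ap2 and cdca7a.

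The row mcm5, named for a subunit of the replicative helicase, had UMIs in 99.6% of cells at 12 hpf and 100% at 72 hpf. Replication proteins in nearly every cell are argued against: mcm2, mcm3, mcm4, mcm6 and mcm7 together had UMIs in 18.1% (16.0 to 20.3) of the 1268 ganglion-like, amacrine-like and bipolar-like cells, all of which had mcm5 UMIs. Heat shock protein 70 reads counted in this row may be the source, since its correlation with hsp70l exceeded its highest with the mcm genes by 0.804 or more in both libraries. In the RefSeq table of GRCz12tu, hsp70.1, hsp70.2 and hsp70.3 lie on the chromosome of mcm5 with 6, 7 and 8 protein-coding genes between, and none has a row of its own in these tables. A gene model of Zv9 was not examined, and no biological explanation was tested beyond expression in every cell.

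The rows btf3l4 and btf3l4.1 tended to exclude each other across 12-hpf cells (Spearman -0.28) and not at 72 hpf (-0.002). Of cells with a btf3l4 UMI 31.0% had one of btf3l4.1, against 72.0% of the others, and btf3l4 led 2 clusters of 187 cells. Reads split between near-identical rows by a variant between embryos could account for this, and then the summed level should be alike: it was 1.44 times (1.3 to 1.59) that of other cells, an interval that spans the bound of 1.5, and a first value, from a less precise clustering that was later replaced, had its interval inside that bound. The cells compared were those of the 2 clusters led by btf3l4, itself 1 of the summed rows. That choice can by itself raise the ratio. By the test set beforehand cell cycle phase also stays open, as the share of cells with btf3l4 UMIs with over without mitosis UMIs was 0.755 (0.499 to 1.14), which just reaches the 2-fold bound. The 2 clusters led by btf3l4, with its UMIs in 76.1% and 85.9% of cells, had mitosis UMIs in 17.4% (10.8 to 25.9) and 100% (95.4 to 100). In these 187 cells of 1 library, high btf3l4 was thus not tied to a single level of mitosis transcripts. The boundaries of these clusters depended on numerical precision. Which embryo a cell came from is not given in the sources used here.

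Ganglion-like cells at 72 hpf carried phototransduction UMIs: gngt2b was in 40.8% of them (median 3750 UMIs) against 72.6% of photoreceptor-like cells (median 4259 UMIs), and rcv1 in 13.3% against 77.6%. Over all 23 genes the ratios of ganglion-like to library CPM differed by 42.2 times beyond counting error, between gnb1b and opn1sw2. That range was set by gnb1b. Both gnb1b (580 against 141 CPM) and gnb1a (263 against 57.7 CPM) were higher in ganglion-like than in photoreceptor-like cells. Free RNA as the only source is thus argued against for these 2 genes only. Without gnb1a and gnb1b the ratios still differed by 3.53 times, between rho and opn1sw2, over the bound of 3 set for all genes, but library CPM includes the expressing cells, so these ratios are alike only if free RNA has the same mix as the captured cells. Between amacrine-like and ganglion-like cells, a comparison that does not need this, free RNA may be the source for 15 of these genes: the ratios ran from 0.621 (gnb3b) to 1.21 (gngt1), and the intervals missed a common ratio by a factor of 1.14, under the bound of 1.5, which leaves this open. Low-level expression in ganglion-like cells was not tested.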
